A study of Mus musculus with 25 samples.

How the data were processed

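RNA sequencing was read in 25 libraries of 14 groups of mouse immune cells, 11 groups with 2 libraries and 3 groups (labelled dendritic cell, eosinophil and macrophage) with 1. Per the labels, RNA was isolated with Isogen or TRIzol LS and libraries were made with a TruSeq RNA v2 kit. The deposited table holds FPKM, fragment numbers that the authors scaled for transcript length and for the mapped fragments of the library. Tools named per the submitters' processing notes are Bowtie2 2.1.0, TopHat2 2.0.8 and Cufflinks 2.1.1, with reads mapped to the mouse genome build mm9; their settings and the gene annotation are not given in the sources used here. Counts and library sizes are not given in the sources used here, so the depth behind each value is unknown and no interval or detection limit is given. Genes are named as in the table, and no coordinates are given because the reference at hand is of another build. The table has 23234 genes. Values at exactly 0 can be estimates that failed, since 39 to 68 genes per group were listed at 0 in one library and at 10 FPKM or more in the other (142 in the group labelled LTi).

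Groups follow the labels. The fit used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) of the 22 libraries of the 11 groups with 2 libraries, with group as the only term, 11 residual degrees of freedom and an intensity trend in the empirical Bayes step. Genes entered when at least 2 of these libraries had an FPKM of at least 1, which left 13446. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1 in a two-sided test. There were 9 contrasts between groups. A gene counted as enriched in 1 of 5 groups when it was higher by at least 1 log2 than every other group compared, each contrast tested one-sided and the largest p adjusted; IL-33 ILC2s were left out of the naive ILC2 comparison. The 3 single libraries gave values without a test. Gene lists fixed before the data were examined (29 lists, 261 list tests) were tested with camera of limma at a preset correlation of 0.01, two-sided and adjusted over all lists and contrasts, and again with the correlation estimated for each list. Some lists share members, such as the type 2 and Th2 lists. The 2 activation contrasts were compared by their log2 fold changes across genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

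Genes were named by a rule written before the data were examined. For each contrast it takes the 5 genes with the largest rise and the 5 with the largest fall that passed, whose libraries in one group all lay beyond those of the other and whose higher group had a mean of at least 10 FPKM. It leaves out unnamed gene models, immunoglobulin and T cell receptor segments, small RNA hosts, chromosome Y genes and Xist. Of each list described it takes up to 4 members with the largest change among those that passed and up to 2 that did not pass where a reader would look for them, and for each enriched set the 8 genes with the largest margin. Genes of the sort gates and cultures were read in every library. Some lists were left undescribed in a contrast, including some that passed, and some genes whose call hung on 1 library were left unnamed. Xist and Ddx3y were read as sample checks after the values were seen.

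The fit was tested on simulated changes of known size in the libraries' layout, and real recovery may be lower. In IL-33 against naive ILC2s, 40%, 94%, 96% and 96% of 50 changed genes were recovered at log2 changes of 1, 2, 3 and 4, with 8 false calls. For genes enriched in B cells the shares were 4%, 92%, 92% and 98%, with 0 false calls. A simulated list shifted by a log2 of 1 was found, as was 1 of 28 unshifted lists.

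Alternatives were a pseudocount of 0.1, no filter, a stricter filter (FPKM of at least 5), libraries rescaled to the same sum, quantile normalization, no intensity trend, replicate number as a block, a fit of only the 2 groups compared, the 3 single libraries added as groups, and each library left out in turn. A library left alone in its group was assumed to vary like the other groups. Leaving out the group labelled LTi, centring each library on its median gene and leaving out NK library 1 were added after the data were seen. With 2 libraries per group, no comparison with other splits of the samples and no test for outlying samples within a group could be made.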

Results

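Gene expression was compared across 14 immune cell groups of C57BL/6 wild-type mice in 25 libraries. Innate lymphoid cells of group 2 (ILC2s) from mesentery were read either without culture (naive) or after 48 h with IL-33 at 10 ng/ml. CD4 T cells, CD8 T cells, CD19+ B cells and NK1.1+ Thy1.2- NK cells came from spleen, and so did the single libraries labelled dendritic cell, eosinophil and macrophage. Th1, Th2 and Th17 cells were induced from CD4+ CD62L+ cells for 7 days on plates with anti-CD3ε and anti-CD28. Cells labelled LTi (lymphoid tissue inducer) were grown for 16 days with IL-7 and TSt4/N cells from fetal liver progenitors of embryonic day 13, and mast cells were grown from bone marrow for 4 weeks with IL-3. No label says if a group's 2 libraries came from separate animals. Each p-value measures only sample spread, which may be technical where sex-linked transcripts match. Levels are FPKM as deposited, means of 2 libraries unless stated, with the first-named group first.

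Genes named in the sort gates and cultures were read first, each in the groups that the labels name it for. Cd4 read 255 and 259 FPKM in the CD4 T cell libraries and 0.0752 and 0.265 in the CD8 T cell libraries, where Cd8a read 396 and 409.8. Cd19 read 607 and 615 FPKM in B cells, Klrb1c (NK1.1) 721 and 636 in NK cells, and Fcer1a, the alpha chain of the high-affinity IgE receptor, 5311 and 4446 in mast cells. Kit, the stem cell factor receptor in the mast cell gate, read 814 and 434 FPKM in mast cells. Tbx21, which encodes T-bet, read 95.99 and 99.8 FPKM in Th1 cells against 6.33 and 7.11 in Th2 cells, and Gata3 read 116 and 118 in Th2 cells against 2.21 and 1.72 in Th1 cells. Rorc, which encodes RORγt, read 53.7 and 51.2 FPKM in Th17 cells and 10.1 and 1.34 in Th1 cells. Gata3 was higher still in naive ILC2s, at 540.0 and 569.8 FPKM, and read 104 and 107 in IL-33 ILC2s. Sex-linked Xist and Ddx3y differed inside some groups: NK 1 read 20.7 and 2.44 FPKM and NK 2 1.15 and 20.01. Mast 1 read 69.7 and 0.0151 and mast 2 11.2 and 21.2. Naive ILC2s read 41.3 and 0.0364, so sex may add to their contrasts with NK cells and the group labelled LTi.

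The pair labelled LTi was the exception. MHC class II and dendritic cell genes filled the library labelled LTi 1, where H2-Ab1 read 6968 FPKM, Cd74 14256, Itgax (CD11c) 410.1 and Flt3 126, while Rorc read 0.342 and Il7r 10.6. In the library labelled LTi 2, Rorc read 167 FPKM, Il7r 640.3 and Thy1 419. The library labelled dendritic cell held 169 FPKM of Rorc, 642 of Il7r and 435 of Thy1 beside 3.71 of Itgax and 9.25 of H2-Ab1. Across genes, LTi 1 and LTi 2 correlated at r = 0.775 and 3640 genes lay more than 1 log2 apart, whereas the libraries labelled LTi 2 and dendritic cell correlated at r = 0.973. The other pairs of replicates had r between 0.953 and 0.984, across genes, which are not independent replicates. All groups follow the labels throughout, so the group labelled LTi joins these unlike libraries.

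**Figure D1:**
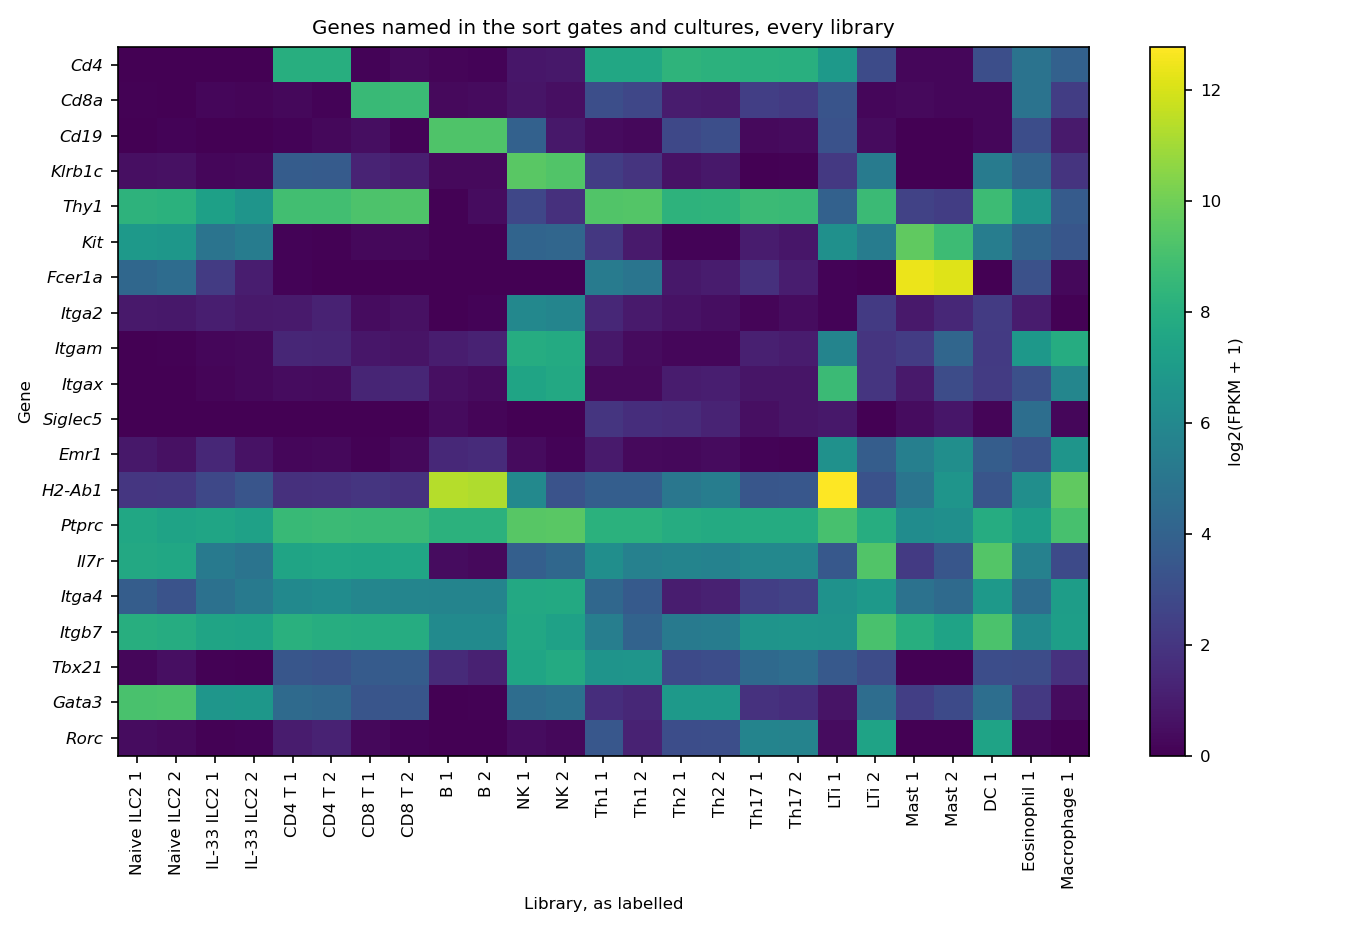
Level of each gene named in the sort gates and cultures (one gene per line of the map) in each of the 25 libraries as labelled, as log2(FPKM + 1) on the colour scale. Rorc, Il7r and Thy1 are high in the libraries labelled LTi 2 and DC 1, and Itgax and H2-Ab1 are high in the library labelled LTi 1.

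**Figure D2:**
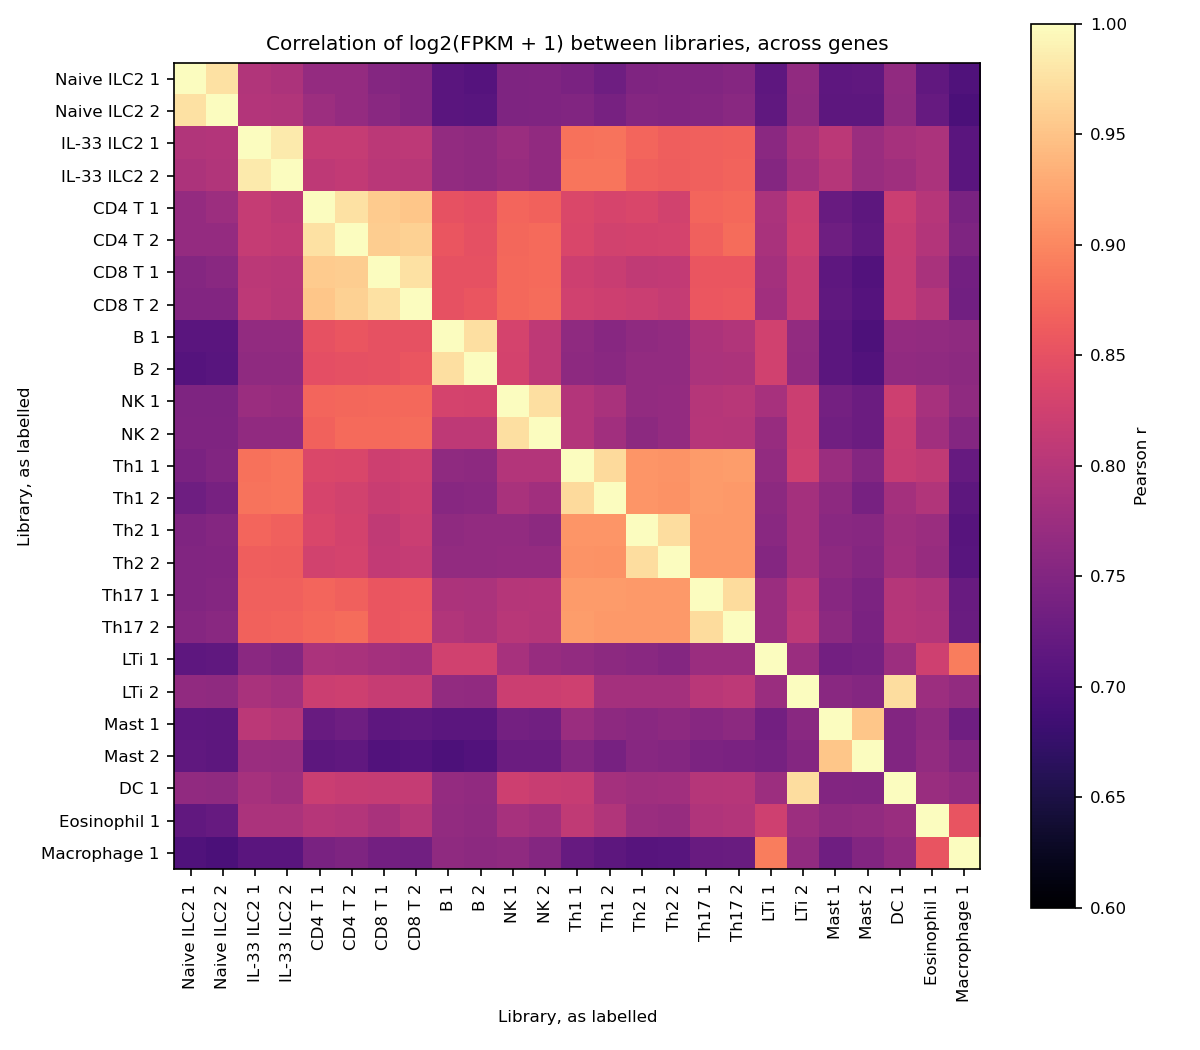
Pearson r of log2(FPKM + 1) across genes between every pair of the 25 libraries as labelled, on the colour scale. Pairs of the same group are bright squares except LTi 1 with LTi 2 (0.775). LTi 2 with DC 1 (0.973) is as bright as a pair of replicates, and CD4 T with CD8 T libraries (up to 0.961) are as bright as the mast cell pair (0.953).

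In ILC2s cultured with IL-33, proliferation, glycolysis and cholesterol synthesis genes rose and immediate early genes fell. No ILC2s were cultured without IL-33, so IL-33, culture and handling cannot be told apart. Il9, a type 2 cytokine, rose from 2.43 ± 1.02 to 1989 ± 771 FPKM (SD, n = 2 and 2, log2 fold change 9.16 on the log2(FPKM + 1) scale of the fit). Cyp11a1, the enzyme that opens steroid synthesis, rose to 218 ± 24.5 FPKM (log2 fold change 7.52), and the desaturase Scd2 rose too (7.10). Fosb, an AP-1 subunit, fell from 697 ± 117 to 0.245 ± 0.0319 FPKM. Of 13446 genes tested, 5753 passed (limma with Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1), 4616 higher and 1137 lower after IL-33. That split rested on scaling: the median log2 fold change of all genes was 0.51 as deposited, 0.01 after quantile normalization (2403 higher, 2132 lower) and -0.34 with each library centred on its median gene (1953 higher, 2955 lower). Directions of the lists and named genes here held under these scalings, except as stated for Il5, Il2ra and the type 2 list.

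Cell cycle genes rose as a block. Birc5 (survivin) read 134 against 0.549 FPKM (log2 fold change 6.45, SE 0.54, adjusted p = 1.63e-07), topoisomerase Top2a 147 against 0.812 FPKM, cyclin B1 (Ccnb1) 79.4 against 0.106 FPKM and cyclin A2 (Ccna2) 93.2 against 0.381 FPKM. Among 29 proliferation genes, 29 rose, 0 fell and 0 did not pass (29 and 0 adjusted over the list alone). Proliferation genes as a set had camera adjusted p = 4.86e-07 and adjusted p = 0.605 with an estimated correlation. Glycolytic enzymes rose with them, led by Tpi1 at 663 against 31.1 FPKM, Pgam1 at 538 against 33.6 FPKM and Pgk1 at 1419 against 97.7 FPKM. In the glycolysis list of 20, 16 rose, 0 fell and 4 did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 0.00461, adjusted p = 0.49 with an estimated correlation), and without the group labelled LTi in the fit the estimated-correlation value was 0.0353. Cholesterol synthesis genes included Fdps (240.2 against 14.8 FPKM, log2 fold change 3.93), Lss (51.05 against 2.87 FPKM) and Idi1 (151 against 15.2 FPKM). Of the 22 on that list, 18 rose, 1 fell and 3 did not pass (18 and 1 adjusted over the list alone). Cholesterol genes as a set had camera adjusted p = 0.00256 and adjusted p = 0.62 with an estimated correlation.

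Genes of protein folding and secretion rose too, among them the chaperone cofactor Sdf2l1 (185 against 3.17 FPKM, log2 fold change 5.49), and the disulfide isomerases Pdia4 (131 against 8.85 FPKM) and Pdia6 (381 against 39.2 FPKM). In the unfolded protein response and secretory list of 20, 13 rose, 1 fell and 6 did not pass (13 and 1 adjusted over the list alone, camera adjusted p = 0.0474, adjusted p = 0.49 with an estimated correlation), and the camera call was lost with the stricter filter (adjusted p = 0.104), without the intensity trend (0.0515) and with the replicate block (0.0514). Serine synthesis genes Psat1 (149 against 8.58 FPKM) and Phgdh (95.1 against 8.05 FPKM) rose, as did asparagine synthetase Asns (22.8 against 0.351 FPKM). The amino acid and one-carbon list of 17 gave no call as a set, although 10 rose, 3 fell and 4 did not pass (10 and 3 adjusted over the list alone). Amino acid genes as a set had camera adjusted p = 0.56.

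Type 2 effector genes moved apart. Il9 and Tph1, which makes the first step of serotonin synthesis (78.3 against 1.51 FPKM), rose, while the chemokine Ccl1 (16.1 against 323 FPKM) and amphiregulin (Areg, 47.9 against 672 FPKM, log2 fold change -3.78) fell. Il5 was high on both sides, and its fold fell short of the threshold (3759.7 ± 707 against 2584 ± 797 FPKM, log2 fold change 0.56, adjusted p = 0.0431), and its change was -0.29 under median centring. Il4 did not pass either (21.5 against 38.2 FPKM, log2 fold change -0.81), but passed as lower after quantile normalization (-1.31), median centring (-1.66) and without IL-33 library 2 (-1.10) or naive library 1 (-1.03). Il13, added after its values were seen, read 724 and 1077 FPKM in the naive libraries and 4124 and 5524 after IL-33. Over the 14 genes, 4 rose, 3 fell and 7 did not pass (4 and 3 adjusted over the list alone, camera adjusted p = 0.391), with a median log2 fold change of 0.17, a mean of 0.54 and a camera direction of down, and the median was negative after quantile normalization and median centring. ILC2 receptors and regulators fell on balance: Ramp3, a receptor activity modifying protein, read 104 against 1112 FPKM, the transcription factor Rora 27.5 against 255 FPKM and the IL-25 receptor Il17rb 5.15 against 50.96 FPKM, whereas the neuromedin U receptor Nmur1 rose (39.6 against 3.69 FPKM). Of 26 such genes, 2 rose, 11 fell and 13 did not pass (2 and 11 adjusted over the list alone). ILC2 receptors and regulators as a set had camera adjusted p = 5.64e-06 and adjusted p = 0.209 with an estimated correlation, or 0.0225 without the group labelled LTi. Il2ra did not pass, with 491 against 487 FPKM and a log2 fold change of 0.01 (-0.06 with libraries scaled to the same sum, -0.84 under median centring), and Il7r did not pass at 33.4 against 199 FPKM (adjusted p = 0.0757) but passed at the same fold without the group labelled LTi (adjusted p = 5.48e-06).

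The sharpest falls were in immediate early genes, which respond within minutes to many stimuli. Fos read 3.07 against 669.5 FPKM, the orphan nuclear receptor Nr4a3 0.698 against 513 FPKM and Klf4 0.736 against 479 FPKM (log2 fold change -8.11, SE 0.62, adjusted p = 5.57e-08), and the chemokine Cxcl1 fell with them (0.364 against 225 FPKM). Of 26 immediate early and stress genes, 0 rose, 23 fell and 3 did not pass (0 and 23 adjusted over the list alone). Immediate early genes as a set had camera adjusted p = 6.23e-14 and adjusted p = 0.127 with an estimated correlation, or 0.0425 without the group labelled LTi. NF-kB feedback genes fell alike: Tnfaip3 (A20) read 38.95 against 1283 FPKM, Nfkbie 7.53 against 204 FPKM and Nfkbia 140.1 against 1683 FPKM. On the NF-kB list of 16, 0 rose, 11 fell and 5 did not pass (0 and 11 adjusted over the list alone). NF-kB genes as a set had camera adjusted p = 1.68e-08 and adjusted p = 0.0765 with an estimated correlation, or 0.00688 without the group labelled LTi. Genes that mark other cells fell alongside, including the haemoglobin genes Hbb-b2 (0.484 against 84.4 FPKM) and Hba-a1 (7.13 against 130.1 FPKM). Their near-identical copies make the split between them uncertain. The matrix gene Dcn fell too (0.223 against 79.4 FPKM). For the 5 erythroid genes, 0 rose, 5 fell and 0 did not pass (0 and 5 adjusted over the list alone). Erythroid genes as a set had camera adjusted p = 0.0019 and adjusted p = 0.183 with an estimated correlation, or 0.0365 without the group labelled LTi. Of 15 stromal and adipose genes, 1 rose, 4 fell and 10 did not pass (1 and 4 adjusted over the list alone, camera adjusted p = 7.28e-04, adjusted p = 0.431 with an estimated correlation), and Lum rose (19.05 against 4.19 FPKM), while without the group labelled LTi 9 fell. Mast cell genes fell as well: of 16, 1 rose, 8 fell and 7 did not pass (1 and 8 adjusted over the list alone). Mast cell genes as a set had camera adjusted p = 7.00e-04 and adjusted p = 0.301 with an estimated correlation. Of 13 naive and homing genes, 0 rose, 6 fell and 7 did not pass (0 and 6 adjusted over the list alone). Naive and homing genes as a set had camera adjusted p = 0.00121 and adjusted p = 0.127 with an estimated correlation. Median centring ended the camera calls of the erythroid (adjusted p = 0.0744) and stromal lists (0.0754).

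**Figure D3:**
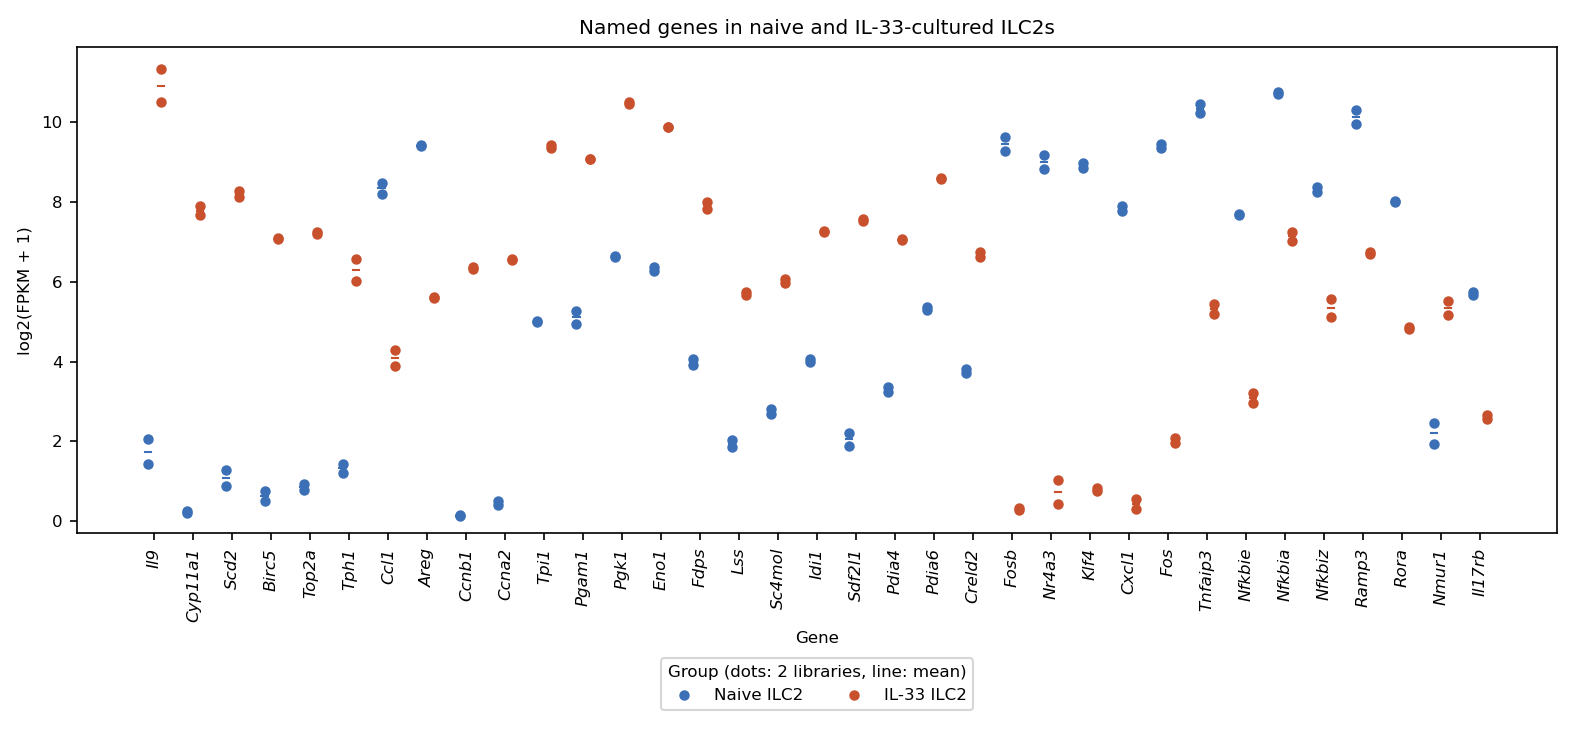
Level of the named genes in naive and IL-33-cultured ILC2s as log2(FPKM + 1), with a dot for each of the 2 libraries and a line at their mean. Il9 stands at 1989 against 2.43 FPKM and Fosb at 0.245 against 697 FPKM (IL-33 against naive), and the dots of a group lie close together beside the distance between the groups for most of them.

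IL-33-cultured ILC2s were next set against Th2 cells, the T helper cells that make the same type 2 cytokines. Arginase 1 (Arg1) read 336 ± 37.4 against 1.09 ± 0.242 FPKM (SD, n = 2 and 2), the receptor Klrg1 227 ± 9.62 against 0.687 ± 0.129 FPKM, and the triglyceride enzyme Dgat2 94.3 against 0.551 FPKM. Il9 (1989 against 17.2 FPKM) and Il6 (204 against 2.15 FPKM) were higher in ILC2s. Lower in ILC2s were Folr4, a folate receptor family member of T cells (0.027 against 589.8 FPKM), the cytokine Il24 (0.234 against 438 FPKM) and the adhesion molecule Cd2 (0.551 against 444 FPKM). Cd4 and the hydroxysteroid dehydrogenase Akr1c18 were listed at 0 in both ILC2 libraries and at 312 and 289 FPKM and 449.7 and 435 FPKM in Th2 cells. In all, 2633 genes passed, 1465 higher and 1168 lower in ILC2s (limma with Benjamini-Hochberg), or 1173 and 1227 after quantile normalization and 1834 and 1162 with libraries scaled to the same sum.

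Type 2 genes were divided between the cells, with Arg1, Il9 and Il6 higher in ILC2s and Il10 lower (0.11 against 44.5 FPKM, log2 fold change -5.36), while Areg did not pass (47.9 against 61.2 FPKM). Of 14 type 2 genes, 8 rose, 3 fell and 3 did not pass (9 and 3 adjusted over the list alone). Type 2 genes as a set had camera adjusted p = 0.163. The proliferation list was higher throughout in ILC2s, as in the replication licensing gene Cdc6 (25.8 against 2.94 FPKM), the kinase Plk1 (52.9 against 9.10 FPKM) and Rrm2 (232 against 45.5 FPKM). For its 29 genes, 29 rose, 0 fell and 0 did not pass (29 and 0 adjusted over the list alone). Proliferation genes as a set had camera adjusted p = 1.92e-07 and adjusted p = 0.605 with an estimated correlation. Secretory pathway genes such as Creld2 (101 against 20.6 FPKM) and the chaperone Hsp90b1 (738 against 164 FPKM, log2 fold change 2.17, SE 0.27) were also higher in ILC2s, but the stress factor Ddit3 (CHOP) was lower (7.34 against 78.99 FPKM). Over 20 secretory pathway genes, 14 rose, 1 fell and 5 did not pass (14 and 1 adjusted over the list alone). Secretory pathway genes as a set had camera adjusted p = 3.43e-04 and adjusted p = 0.166 with an estimated correlation.

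Genes of the T cell receptor complex and its partners were far lower in ILC2s, where Cd5 read 0.016 against 227 FPKM, Cd3d 0.858 against 263 FPKM (log2 fold change -7.15, SE 0.37, adjusted p = 5.96e-09) and Cd6 0.251 against 120.0 FPKM. The kinases Zap70 (63.96 against 135 FPKM, log2 fold change -1.07) and Itk (91.5 against 183 FPKM) did not pass, and Zap70 passed at the same fold without the group labelled LTi (adjusted p = 9.83e-06). Of the 16 T cell genes, 0 rose, 13 fell and 3 did not pass (0 and 13 adjusted over the list alone). T cell genes as a set had camera adjusted p = 6.20e-10 and adjusted p = 8.22e-04 with an estimated correlation. Regulatory T cell genes Ctla4 (10.6 against 365 FPKM) and Tnfrsf4 (OX40, 27.3 against 367 FPKM) were lower in ILC2s, while Foxp3 (0.0452 against 0.291 FPKM) and Il2ra (491 against 674 FPKM) did not pass. In the regulatory T cell list of 13, 0 rose, 8 fell and 5 did not pass (0 and 8 adjusted over the list alone). Regulatory T cell genes as a set had camera adjusted p = 6.57e-06 and adjusted p = 0.00629 with an estimated correlation. Cytotoxic genes were lower too, with granzyme B (Gzmb) at 0.125 against 294 FPKM and Nkg7 at 0.249 against 113 FPKM. Of 18 cytotoxic and NK genes, 0 rose, 10 fell and 8 did not pass (0 and 10 adjusted over the list alone). Cytotoxic genes as a set had camera adjusted p = 1.28e-07 and adjusted p = 0.00245 with an estimated correlation. Naive T cell genes followed, with the transcription factors Tcf7 (1.92 against 55.7 FPKM) and Lef1 (1.49 against 36.1 FPKM) and the exit receptor S1pr1 (1.20 against 21.8 FPKM) lower in ILC2s, and Il7r did not pass (33.4 against 51.7 FPKM). Among 13 naive and homing genes, 1 rose, 9 fell and 3 did not pass (1 and 9 adjusted over the list alone). Naive and homing genes as a set had camera adjusted p = 9.30e-05 and adjusted p = 0.0765 with an estimated correlation.

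Th2 cells were compared with the CD4 T cells of spleen. Il13 and the parathyroid hormone gene Pth were listed at 0 in both CD4 T cell libraries and read 1088 and 1121 FPKM and 816 and 813 FPKM in Th2 cells. Il24 was likewise listed at 0 in CD4 T cells, with 409 and 467 FPKM in Th2 cells, while Akr1c18 rose to 442 against 0.0401 FPKM and osteopontin (Spp1) to 416 against 0.203 FPKM (log2 fold change 8.43, SE 1.25). The quiescence factor Klf2 fell from 159.7 ± 20.5 to 0.488 ± 0.268 FPKM (SD, n = 2 and 2), L-selectin (Sell) read 3.94 against 391 FPKM, and Nsg2, Ms4a4b and Pydc3 fell (0.281 against 139, 9.58 against 837 and 0.118 against 84.5 FPKM). Past the threshold were 3386 genes, 1858 higher and 1528 lower in Th2 cells (limma with Benjamini-Hochberg). With each library scaled to the same sum these were 1750 higher and 2186 lower, and the median log2 fold change of all genes was -0.13 in place of 0.

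Type 2 genes rose as a set, with the enkephalin precursor Penk at 750.0 against 2.23 FPKM, Il5 at 217 against 0.0245 FPKM and Areg at 61.2 against 0.182 FPKM. Of 14 type 2 genes, 12 rose, 0 fell and 2 did not pass (12 and 0 adjusted over the list alone). Type 2 genes as a set had camera adjusted p = 1.43e-07 and adjusted p = 0.00433 with an estimated correlation. For the Th2 list of 13, 12 rose, 0 fell and 1 did not pass (12 and 0 adjusted over the list alone). Th2 genes as a set had camera adjusted p = 1.43e-07 and adjusted p = 0.101 with an estimated correlation, or 0.0281 without the group labelled LTi. On that list, Cyp11a1 was listed at 0 in CD4 T cells and at 67.9 and 73.96 FPKM in Th2 cells, while Maf did not pass (27.3 against 13.99 FPKM, log2 fold change 0.92). Glycolytic genes rose, such as Aldoc (50.7 against 1.05 FPKM), the lactate exporter Slc16a3 (38.8 against 1.18 FPKM) and hexokinase 2 (Hk2, 17.4 against 0.219 FPKM). Of the 20, 14 rose, 1 fell and 5 did not pass (14 and 1 adjusted over the list alone). Glycolysis genes as a set had camera adjusted p = 1.43e-07 and adjusted p = 0.144 with an estimated correlation, or 0.00393 without the group labelled LTi. Cholesterol synthesis rose through Fdft1 (65.03 against 8.30 FPKM) and Hmgcs1 (66.1 against 8.50 FPKM, log2 fold change 2.82), and of 22 genes 17 rose, 0 fell and 5 did not pass (17 and 0 adjusted over the list alone). Cholesterol genes as a set had camera adjusted p = 1.68e-08 and adjusted p = 0.237 with an estimated correlation. Lipid genes included the desaturase Scd1 (51.001 against 0.273 FPKM), the nuclear receptor Pparg (31.7 against 0.232 FPKM) and the carrier Fabp5 (89.8 against 6.31 FPKM). On the fatty acid list of 19, 9 rose, 0 fell and 10 did not pass (9 and 0 adjusted over the list alone). Fatty acid genes as a set had camera adjusted p = 2.19e-04 and adjusted p = 0.153 with an estimated correlation, or 0.0479 without the group labelled LTi.

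Asns (88.6 against 0.459 FPKM), Psat1 (149 against 15.5 FPKM) and the amino acid transporter Slc7a5 (75.1 against 14.3 FPKM) rose in Th2 cells. Over the 17 amino acid and one-carbon genes, 9 rose, 0 fell and 8 did not pass (9 and 0 adjusted over the list alone). Amino acid genes as a set had camera adjusted p = 5.21e-04 and adjusted p = 0.0252 with an estimated correlation, which became 0.0961 without the group labelled LTi. Proliferation genes rose from low levels, with Aurkb at 19.3 against 1.90 FPKM and Cdk1 at 16.3 against 1.44 FPKM. In that list of 29, 20 rose, 0 fell and 9 did not pass (20 and 0 adjusted over the list alone). Proliferation genes as a set had camera adjusted p = 2.24e-05 and adjusted p = 0.682 with an estimated correlation. Naive T cell genes fell, as in Klf2, Sell and Igfbp4 (11.9 against 293 FPKM), and Tcf7 read 55.7 against 749.7 FPKM. Il7r did not pass (51.7 against 182 FPKM) but passed at the same fold without the group labelled LTi (adjusted p = 1.96e-04). Of 13 naive and homing genes, 0 rose, 11 fell and 2 did not pass (0 and 11 adjusted over the list alone). Naive and homing genes as a set had camera adjusted p = 1.01e-04 and adjusted p = 0.0765 with an estimated correlation. Interferon-stimulated genes fell, such as Ifit2 (1.23 against 20.98 FPKM), Ifit3 (0.0828 against 8.50 FPKM) and the interferon regulatory factor Irf7 (4.78 against 46.1 FPKM). In the interferon list of 20, 1 rose, 14 fell and 5 did not pass (1 and 14 adjusted over the list alone). Interferon-stimulated genes as a set had camera adjusted p = 5.13e-04 and adjusted p = 0.502 with an estimated correlation. Beside the type 2 genes, some mast cell genes rose, with Cd63 at 20.3 against 0.0468 FPKM, the granule proteoglycan Srgn at 2325 against 269 FPKM and the chymase Cma1 at 9.19 against 0.283 FPKM. Of 16 mast cell genes, 8 rose, 0 fell and 8 did not pass (8 and 0 adjusted over the list alone). Mast cell genes as a set had camera adjusted p = 0.0067 and adjusted p = 0.475 with an estimated correlation.

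Between Th2 and Th1 cells, the cytokines that name each fate separated widely. Ifng read 4.22 ± 0.535 against 5056 ± 144 FPKM (SD, n = 2 and 2, log2 fold change -9.92). Il5 read 217 ± 15.3 against 0.455 ± 0.556 FPKM and Il13 1104 ± 23.5 against 6.89 ± 2.31 FPKM. Pth (815 against 0.227 FPKM), the chemokine Cxcl3 (61.96 against 0.209 FPKM) and Akr1c18 (442 against 9.62 FPKM) were higher in Th2 cells, and the chemokines Ccl3 (8.06 against 3325 FPKM), Ccl4 (9.39 against 2611 FPKM), Xcl1 (1.11 against 245 FPKM) and Ccl9 (2.12 against 246 FPKM) were lower. The count past the threshold was 1526, 617 higher and 909 lower in Th2 cells (limma with Benjamini-Hochberg). After quantile normalization it was 775 higher and 605 lower, and the median log2 fold change of all genes was -0.01 in place of -0.14.

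Ccl5 (22.3 against 1527 FPKM) and Tbx21 (6.72 against 97.9 FPKM, log2 fold change -3.68, SE 0.18, adjusted p = 6.88e-09) were lower in Th2 cells, whereas Il18r1 (16.7 against 86.98 FPKM) and Eomes (1.38 against 3.48 FPKM) did not pass. Il18r1 passed at the same fold, -2.31, without the group labelled LTi (adjusted p = 3.02e-11). Of 15 Th1 genes, 0 rose, 11 fell and 4 did not pass (0 and 11 adjusted over the list alone). Th1 genes as a set had camera adjusted p = 6.96e-06 and adjusted p = 0.0191 with an estimated correlation, which became 0.0522 without the group labelled LTi. Gata3 (117 against 1.97 FPKM, log2 fold change 5.32, SE 0.78) and Epas1 (HIF-2α, 62.1 against 1.86 FPKM) were higher in Th2 cells, and Maf did not pass (27.3 against 19.3 FPKM). For the Th2 list of 13, 11 rose, 1 fell and 1 did not pass (11 and 1 adjusted over the list alone). Th2 genes as a set had camera adjusted p = 2.31e-10 and adjusted p = 0.0527 with an estimated correlation, or 0.0157 without the group labelled LTi. Cytotoxic genes were lower, among them perforin (Prf1, 8.24 against 276 FPKM), Klrk1 (NKG2D, 1.44 against 52.2 FPKM) and Klrd1 (CD94, 3.95 against 86.8 FPKM), while Fasl did not pass (6.62 against 13.5 FPKM, log2 fold change -0.94). Of 18 cytotoxic and NK genes, 1 rose, 11 fell and 6 did not pass (1 and 11 adjusted over the list alone). Cytotoxic genes as a set had camera adjusted p = 4.86e-07 and adjusted p = 0.00303 with an estimated correlation.

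Cholesterol synthesis genes were modestly higher in Th2 cells, with Mvd at 56.5 against 20.6 FPKM and Insig1 at 65.1 against 27.6 FPKM. Of the 22, 9 rose, 0 fell and 13 did not pass (9 and 0 adjusted over the list alone). Cholesterol genes as a set had camera adjusted p = 3.25e-07 and adjusted p = 0.285 with an estimated correlation. Proliferation genes were lower, as in cyclin E2 (Ccne2, 1.69 against 9.70 FPKM) and Aurka (11.8 against 47.9 FPKM), and the call of Birc5 (25.2 against 111 FPKM, adjusted p = 0.00802) was lost without Th2 library 1 (adjusted p = 0.0569). In that list of 29, 0 rose, 24 fell and 5 did not pass (0 and 26 adjusted over the list alone). Proliferation genes as a set had camera adjusted p = 1.53e-06 and adjusted p = 0.62 with an estimated correlation. Mast cell genes were higher in Th1 than in Th2 cells: Fcer1a read 0.846 against 34.2 FPKM, the carboxypeptidase Cpa3 3.94 against 56.8 FPKM and Hdc, which makes histamine, 1.11 against 9.69 FPKM. Over 16 mast cell genes, 1 rose, 9 fell and 6 did not pass (1 and 9 adjusted over the list alone, camera adjusted p = 0.0385, adjusted p = 0.605 with an estimated correlation), and the camera call was lost with pseudocount 0.1 (adjusted p = 0.0722), the stricter filter (0.0663), scaling to the same sum (0.0731), or without the group labelled LTi (0.116). Of the B cell genes, only Cd19 (6.67 against 0.248 FPKM, adjusted p = 0.0266) and Cd79b (11.7 against 0.623 FPKM, adjusted p = 0.043) passed as higher in Th2 cells. Leaving out any of the 4 libraries ended both calls, with adjusted p from 0.0798 to 0.118 for Cd19 and from 0.111 to 0.159 for Cd79b. Of 14 B cell genes, 2 rose, 0 fell and 12 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.0367, adjusted p = 0.744 with an estimated correlation), and quantile normalization ended the camera call (adjusted p = 0.175).

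**Figure D4:**
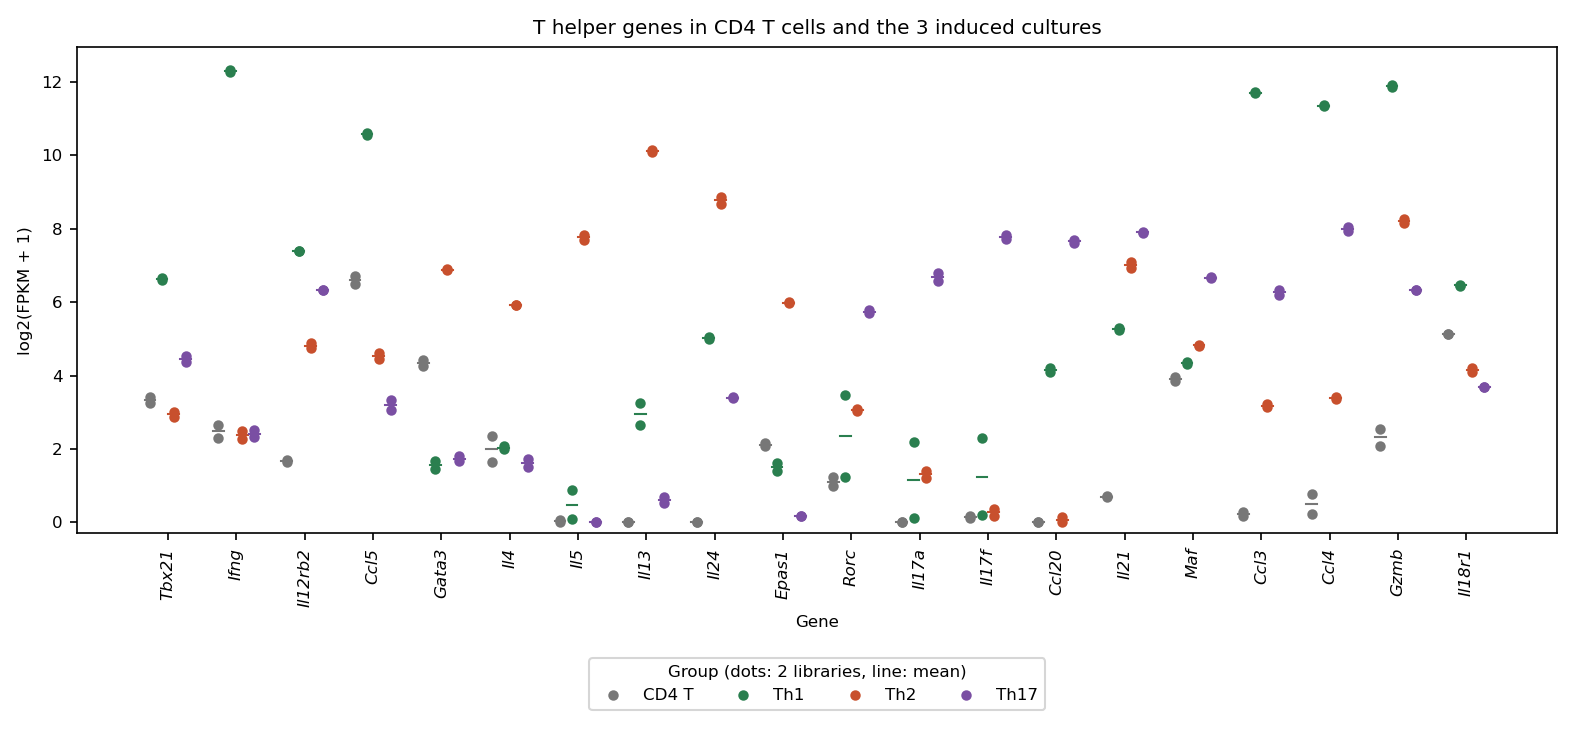
Level of T helper genes, chosen for display after their values were seen, in CD4 T cells and in Th1, Th2 and Th17 cells as log2(FPKM + 1), with a dot per library and a line at the mean of the 2 libraries. Ifng stands highest in Th1 cells (5056 FPKM), Il13 in Th2 cells (1104 FPKM) and Il17a in Th17 cells (102 FPKM).

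Th17 cells differed from Th1 cells first in their cytokines. Il17f read 219 ± 10.04 against 2.02 ± 2.64 FPKM and Il17a 102 ± 11.96 against 1.82 ± 2.47 FPKM (SD, n = 2 and 2). The Th1 libraries differed, with 3.89 and 0.155 FPKM of Il17f and 3.57 and 0.0778 of Il17a. Igfbp4 (584 against 31.5 FPKM), the costimulatory ligand Cd86 (28.7 against 0.585 FPKM) and the pseudogene Pisd-ps1 (34.7 against 0.133 FPKM) were also higher in Th17 cells. Ifng was lower (4.35 ± 0.499 against 5056 ± 144 FPKM), and so were the granzymes Gzmd (0.527 against 529 FPKM), Gzme (0.377 against 318 FPKM) and Gzmg (0.318 against 156 FPKM), whose close sequences leave the share of each uncertain. Altogether 1285 genes passed, 640 higher and 645 lower in Th17 cells (limma with Benjamini-Hochberg), or 857 and 650 with libraries scaled to the same sum.

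The chemokine Ccl20 (201 against 16.7 FPKM, log2 fold change 3.51, SE 0.11, adjusted p = 1.03e-10) and the aryl hydrocarbon receptor Ahr (12.7 against 1.07 FPKM) were higher in Th17 cells. Rorc did not pass (52.4 against 5.71 FPKM, log2 fold change 3.39, adjusted p = 0.0906) but passed at the same fold without the group labelled LTi (adjusted p = 4.50e-05), and Irf4 did not pass (239 against 119 FPKM). Of 17 Th17 genes, 8 rose, 0 fell and 9 did not pass (10 and 0 adjusted over the list alone). Th17 genes as a set had camera adjusted p = 4.89e-05 and adjusted p = 0.123 with an estimated correlation. Th1 genes fell alongside Ifng, with Ccl5 at 8.26 against 1527 FPKM, Gzmb at 79.4 against 3794 FPKM and the transcription factor Hlx at 0.731 against 13.004 FPKM, while Il18r1 did not pass (11.9 against 86.98 FPKM) but passed without the group labelled LTi (adjusted p = 6.46e-12). In the Th1 list of 15, 0 rose, 9 fell and 6 did not pass (0 and 9 adjusted over the list alone). Th1 genes as a set had camera adjusted p = 5.51e-06 and adjusted p = 0.0185 with an estimated correlation, which became 0.0555 without the group labelled LTi. Gzma (5.66 against 515 FPKM) and Prf1 (3.67 against 276 FPKM) were lower, and of 18 cytotoxic and NK genes 0 rose, 13 fell and 5 did not pass (0 and 13 adjusted over the list alone). Cytotoxic genes as a set had camera adjusted p = 2.03e-10 and adjusted p = 8.22e-04 with an estimated correlation.

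Several genes of the type 2 list were also lower in Th17 than in Th1 cells, namely Il3 (0.46 against 55.1 FPKM), Il10 (3.93 against 149.8 FPKM, log2 fold change -4.93) and Penk (18.7 against 383 FPKM). Ccl1 was listed at 0 in both Th17 libraries and at 37.1 and 50.01 FPKM in Th1 cells, and Il4 did not pass (2.09 against 3.08 FPKM). Over 14 type 2 genes, 1 rose, 7 fell and 6 did not pass (1 and 7 adjusted over the list alone). Type 2 genes as a set had camera adjusted p = 1.30e-04 and adjusted p = 0.0277 with an estimated correlation, which became 0.0555 without the group labelled LTi. Mast cell genes were lower in Th17 than in Th1 cells, with the IL-33 receptor Il1rl1 at 0.623 against 22.9 FPKM, Fcer1a at 1.73 against 34.2 FPKM and Cpa3 at 7.13 against 56.8 FPKM. Of the 16, 0 rose, 9 fell and 7 did not pass (0 and 9 adjusted over the list alone). Mast cell genes as a set had camera adjusted p = 1.70e-05 and adjusted p = 0.183 with an estimated correlation.

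Set against Th2 cells, Th17 cells again stood apart by cytokines and chemokines. Ccl20 read 201 ± 9.03 against 0.0577 ± 0.0816 FPKM (SD, n = 2 and 2), Il17f 219 ± 10.04 against 0.208 ± 0.107 FPKM and Il17a 102 against 1.48 FPKM. Igfbp4 (584 against 11.9 FPKM) and the interferon-inducible GTPase Iigp1 (44.6 against 0.146 FPKM) were higher in Th17 cells. Il13 (0.528 against 1104 FPKM), Pth (0.148 against 815 FPKM), Akr1c18 (2.29 against 442 FPKM) and Epas1 (0.135 against 62.1 FPKM) were lower, and Il5 was listed at 0 in both Th17 libraries and at 228 and 206 FPKM in Th2 cells. A total of 1305 genes passed, 796 higher and 509 lower in Th17 cells (limma with Benjamini-Hochberg). The split became 1261 and 486 with libraries scaled to the same sum and 587 and 617 after quantile normalization, with median log2 fold changes of all genes of 0.27 and 0.01 in place of 0.11.

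The chemokine receptor Ccr6, which marks Th17 cells, read 24.5 against 0.361 FPKM (log2 fold change 4.23, SE 0.18, adjusted p = 2.81e-09). Rorc (52.4 against 7.31 FPKM, adjusted p = 0.184) and Maf (101 against 27.3 FPKM) did not pass, and both passed at the same folds without the group labelled LTi (adjusted p = 3.05e-04 and 9.31e-08). Of 17 Th17 genes, 7 rose, 2 fell and 8 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.228 with an estimated correlation), and 11 rose without the group labelled LTi. Il24 (9.48 against 438 FPKM) was lower with the other Th2 genes, of which 0 rose, 10 fell and 3 did not pass (1 and 10 adjusted over the list alone). Th2 genes as a set had camera adjusted p = 1.07e-11 and adjusted p = 0.042 with an estimated correlation. On the type 2 list of 14, with Penk at 18.7 against 750.0 FPKM and Il4 at 2.09 against 59.6 FPKM, 0 rose, 10 fell and 4 did not pass (0 and 10 adjusted over the list alone). Type 2 genes as a set had camera adjusted p = 6.46e-13 and adjusted p = 8.22e-04 with an estimated correlation. Proliferation genes were higher in Th17 cells, as in Top2a (214 against 48.7 FPKM) and Ccna2 (85.6 against 23.6 FPKM). Mki67 (71.7 against 15.8 FPKM, log2 fold change 2.12) lost its call without Th2 library 1 (adjusted p = 0.0507). Of the 29 proliferation genes, 25 rose, 0 fell and 4 did not pass (26 and 0 adjusted over the list alone). Proliferation genes as a set had camera adjusted p = 1.55e-07 and adjusted p = 0.605 with an estimated correlation.

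Naive and homing genes were higher in Th17 than in Th2 cells, with Klf2 at 22.3 against 0.488 FPKM and the lymph node homing receptor Ccr7 at 365 against 24.4 FPKM, while Dapl1 was lower (0.642 against 32.2 FPKM). Of 13 naive and homing genes, 7 rose, 1 fell and 5 did not pass (7 and 1 adjusted over the list alone). Naive and homing genes as a set had camera adjusted p = 0.00548 and adjusted p = 0.183 with an estimated correlation. Of B cell genes, Ebf1 (1.65 against 6.88 FPKM) and Blnk (0.02 against 1.56 FPKM) were lower. Cd19 (0.283 against 6.67 FPKM, adjusted p = 0.0326) lost its call when any of the 4 libraries was left out. In the B cell list of 14, 0 rose, 3 fell and 11 did not pass (0 and 3 adjusted over the list alone, camera adjusted p = 0.0149, adjusted p = 0.706 with an estimated correlation), 7 fell without the group labelled LTi, and quantile normalization ended the camera call (adjusted p = 0.0905).

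Naive ILC2s were compared with the group labelled LTi, which as measured joins a library rich in MHC class II genes and one rich in Rorc. Il5 and Calca, the calcitonin gene-related peptide gene, were listed at 0 in both libraries of that group and read 2021 and 3148 FPKM and 700.4 and 983 FPKM in naive ILC2s. Il13 read 900.4 ± 249 against 0.135 ± 0.0902 FPKM (SD, n = 2 and 2), the sulfotransferase Hs3st1 945 ± 23.1 against 0.36 ± 0.446 FPKM and Il1rl1, the IL-33 receptor, 782 against 1.77 FPKM. Lower in naive ILC2s were Cd7 (0.232 against 559 FPKM), the adaptor Tyrobp (0.536 against 744 FPKM), lysozyme (Lyz2, 1.06 against 480.2 FPKM) and Klrd1 (0.0477 against 181 FPKM). The fit passed 5650 genes, 1156 higher and 4494 lower in naive ILC2s (limma with Benjamini-Hochberg). Scaling moved this split to 2066 and 1963 (quantile normalization) or 2723 and 1316 (median centring), and the median log2 fold change of all genes from -0.61 to -0.06 and 0.23.

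Type 2 genes were higher in naive ILC2s, including Csf2 (GM-CSF, 1430.5 against 10.3 FPKM, log2 fold change 8.27). Of the 14, 13 rose, 0 fell and 1 did not pass (13 and 0 adjusted over the list alone). Type 2 genes as a set had camera adjusted p = 4.40e-13 and adjusted p = 8.22e-04 with an estimated correlation. ILC2 genes Klrg1 (383 against 0.775 FPKM), Ramp3 (1112 against 7.36 FPKM) and Gata3 (555 against 11.5 FPKM) were higher too, and of 26 receptors and regulators 18 rose, 1 fell and 7 did not pass (18 and 1 adjusted over the list alone). ILC2 receptors and regulators as a set had camera adjusted p = 8.63e-14 and adjusted p = 0.0441 with an estimated correlation. Il7r did not pass (199 against 325 FPKM, log2 fold change 1.21, averaging log2 values of 2 unlike LTi libraries). Without LTi library 1 it was -1.68, the opposite direction. Among LTi and ILC3 genes, Cxcr5 (0.133 against 29.9 FPKM) and Ccr6 (0.0599 against 13.1) were lower in naive ILC2s. Cd4 was lower too (0.0109 against 120 in LTi 1 and 6.52 in LTi 2). Il22 (0.472 against 4.89) and Il17f (0.23 against 30.02) did not pass. The latter pair passed without LTi library 1 (log2 fold changes -2.87 and -5.63) and turned positive without LTi library 2 (0.56 and 0.10, not passing). With only these 2 groups fitted, Cd4 (adjusted p = 0.0745) and Cxcr5 (0.117) did not pass. Cxcr6 was higher (549 against 147 FPKM, log2 fold change 4.27), but by only 0.89 without LTi library 1 and with adjusted p = 0.059 without naive ILC2 library 2 and 0.245 with only these 2 groups fitted. In that list of 20, 2 rose, 9 fell and 9 did not pass (2 and 9 adjusted over the list alone). LTi and ILC3 genes as a set had camera adjusted p = 0.874. MHC class II genes were lower, but H2-Aa (2.57 against 4814 FPKM) and H2-Eb1 (1.36 against 2768 FPKM) lost their calls without LTi library 1 (adjusted p = 0.063 and 0.0605) or with only these 2 groups fitted (0.179 and 0.196), and near-identical H2 genes can share reads. Of 9 MHC class II genes, 0 rose, 7 fell and 2 did not pass (0 and 7 adjusted over the list alone, camera adjusted p = 0.736), and under median centring the camera value was 0.0403.

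Against NK cells, naive ILC2s separated by type 2 against cytotoxic genes. Granzyme A (Gzma) read 0.0468 ± 0.0662 against 7004 ± 1353 FPKM (SD, n = 2 and 2, log2 fold change -12.70, SE 0.53), the NK receptor Ncr1 (NKp46) 0.0251 against 913 FPKM, Klrd1 0.0477 against 968 FPKM and Tyrobp 0.536 against 2134 FPKM. Klra8, of the near-identical Klra family, was listed at 0 in both ILC2 libraries and at 915 and 918 FPKM in NK cells. Il5, Il13 and Ramp3 were listed at 0 in both NK libraries and read 2021 and 3148 FPKM, 724 and 1077 FPKM and 977 and 1247 FPKM in naive ILC2s, where Hs3st1 (945 against 0.200 FPKM) and Calca (842 against 0.0567 FPKM) were also higher. Past the threshold lay 5942 genes, 1362 higher and 4580 lower in naive ILC2s (limma with Benjamini-Hochberg). The split was 2020 and 2092 after quantile normalization and 3172 and 1356 under median centring, and the median log2 fold change of all genes was -0.57 as deposited, -0.83 with the same sums, -0.10 after quantile normalization and 0.33 under median centring.

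Type 2 genes were higher in naive ILC2s, and Areg was listed at 0 in both NK libraries and at 676 and 668 FPKM in naive ILC2s. Of the 14, 13 rose, 0 fell and 1 did not pass (13 and 0 adjusted over the list alone). Type 2 genes as a set had camera adjusted p = 2.86e-12 and adjusted p = 8.22e-04 with an estimated correlation. Il1rl1 (782 against 0.0984 FPKM), Il2ra (487 against 1.10 FPKM) and Rora (255 against 1.20 FPKM) were higher, while the shared regulator Id2 did not pass (945 against 622 FPKM, log2 fold change 0.59) but passed under median centring (1.49, adjusted p = 3.62e-04). On the ILC2 list of 26, 21 rose, 1 fell and 4 did not pass (21 and 1 adjusted over the list alone). ILC2 receptors and regulators as a set had camera adjusted p = 8.77e-13 and adjusted p = 0.0541 with an estimated correlation, or 0.00393 without the group labelled LTi. Every cytotoxic and NK gene was lower, with Klre1 at 0.0462 against 851 FPKM: of 18, 0 rose, 18 fell and 0 did not pass (0 and 18 adjusted over the list alone). Cytotoxic genes as a set had camera adjusted p = 1.87e-07 and adjusted p = 0.00252 with an estimated correlation. NF-kB genes were higher in naive ILC2s, with Nfkbia at 1683 against 87.9 FPKM, Tnfaip3 at 1283 against 69.2 FPKM and Nfkb1 at 1102 against 71.7 FPKM (log2 fold change 3.92, SE 0.26, adjusted p = 1.89e-08). Of 16, 15 rose, 0 fell and 1 did not pass (15 and 0 adjusted over the list alone). NF-kB genes as a set had camera adjusted p = 2.31e-10 and adjusted p = 0.0498 with an estimated correlation. Nr4a3 (513 against 4.81 FPKM), Ier3 (64.3 against 0.377 FPKM) and Klf4 (479 against 10.7 FPKM) were higher and the phosphatase Dusp2 lower (1.06 against 219.7 FPKM). In the immediate early list of 26, 18 rose, 2 fell and 6 did not pass (18 and 2 adjusted over the list alone). Immediate early genes as a set had camera adjusted p = 4.95e-08 and adjusted p = 0.278 with an estimated correlation.

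Genes that mark other cells differed beside these. Hba-a1 read 130.1 against 2.30 FPKM and Hbb-b1 28.6 against 0.00997 FPKM, with near-identical copies, and of 5 erythroid genes 5 rose, 0 fell and 0 did not pass (5 and 0 adjusted over the list alone). Erythroid genes as a set had camera adjusted p = 0.00152 and adjusted p = 0.179 with an estimated correlation, or 0.0362 without the group labelled LTi, and median centring ended the camera call (adjusted p = 0.0696). Dcn was listed at 0 in both NK libraries and at 109 and 49.4 FPKM in naive ILC2s. Of 15 stromal and adipose genes, 5 rose, 0 fell and 10 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 2.24e-05, adjusted p = 0.278 with an estimated correlation), and 10 rose without the group labelled LTi. Cd72, a B cell receptor partner, was lower in naive ILC2s (18.3 against 113 FPKM, adjusted p = 0.00111). The B cell genes Cd79a (0.92 against 21.1 FPKM, log2 fold change -2.66) and Ms4a1 (0.087 against 8.49 FPKM, log2 fold change -2.54) were carried by NK library 1, without which they were -0.91 (adjusted p = 0.441) and -1.14 (adjusted p = 0.375). Leaving out either naive ILC2 library also ended both calls, with adjusted p from 0.0747 to 0.117 for Cd79a and from 0.0975 to 0.103 for Ms4a1. Of 14 B cell genes, 0 rose, 8 fell and 6 did not pass (0 and 7 adjusted over the list alone). B cell genes as a set had camera adjusted p = 0.809.

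CD8 and CD4 T cells from the same organ differed in the fewest genes. Cd8a read 403 ± 9.53 against 0.16 ± 0.0751 FPKM and Cd8b1 904 ± 43.3 against 11.99 ± 0.572 FPKM (SD, n = 2 and 2), and Cd4 0.17 ± 0.134 against 257 ± 2.83 FPKM. The amino acid transporter Slc6a19 (21.3 against 0.128 FPKM) and the lipocalin Lcn4 (52.99 against 2.16 FPKM) were higher in CD8 T cells, whereas the CD40 ligand gene Cd40lg (0.596 against 63.5 FPKM) and Zbtb7b (ThPOK), the factor that directs thymocytes to the CD4 fate (0.507 against 51.2 FPKM, log2 fold change -5.11, SE 0.19), were lower. Ppp1r18 was listed at 0 in both CD8 T cell libraries and at 119 and 116 FPKM in CD4 T cells, and every library of the other groups listed it above 0, so a failed estimate cannot be excluded from these values. Haao (25.4 against 0.204 FPKM) lost its call without CD8 T cell library 1 (adjusted p = 0.0524) or CD4 T cell library 2 (adjusted p = 0.0507). The number past the threshold was 255, 103 higher and 152 lower in CD8 T cells (limma with Benjamini-Hochberg), and it was 403 (152 and 251) without the group labelled LTi in the fit.

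Of shared T cell genes, Cd3e (270.4 against 258 FPKM) and Lck (403 against 397 FPKM) did not pass, with log2 fold changes of 0.07 and 0.02 whose sign depended on scaling (-0.03 and -0.08 with the same sums). Of 16 T cell genes, 2 rose, 1 fell and 13 did not pass (2 and 1 adjusted over the list alone, camera adjusted p = 0.429), with a median log2 fold change of -0.06, a mean of 0.09 and a camera direction of up. Regulatory T cell genes were lower in CD8 T cells, led by Foxp3 (0.248 against 16.4 FPKM, log2 fold change -3.80, SE 0.15, adjusted p = 6.57e-09) and Nrp1 (0.382 against 7.35 FPKM), while the integrin Itgae (CD103) was higher (43.8 against 2.41 FPKM). Ikzf2 did not pass (2.02 against 8.33 FPKM) but passed without the group labelled LTi (adjusted p = 2.70e-06). In the regulatory T cell list of 13, 1 rose, 7 fell and 5 did not pass (1 and 9 adjusted over the list alone). Regulatory T cell genes as a set had camera adjusted p = 5.94e-13 and adjusted p = 8.22e-04 with an estimated correlation. Of cytotoxic genes, Nkg7 (407 against 43.2 FPKM) and Klrd1 (201 against 25.7 FPKM) were higher in CD8 T cells, and Fasl was lower (1.04 against 11.1 FPKM). Ctsw (221 against 41.6 FPKM, log2 fold change 2.39) and Eomes (23.7 against 3.35 FPKM, log2 fold change 2.51) did not pass, and both passed at the same folds without the group labelled LTi (adjusted p = 1.95e-07 and 0.0193). Of 18 cytotoxic and NK genes, 5 rose, 2 fell and 11 did not pass (7 and 2 adjusted over the list alone). Cytotoxic genes as a set had camera adjusted p = 1.57e-06 and adjusted p = 0.0039 with an estimated correlation.

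Across the 29 gene lists and 9 comparisons, 102 of 261 list tests passed, 58 up and 44 down, and 21 passed with an estimated correlation. The calls that held with it were the type 2 list in Th2 against CD4 T cells, in Th17 against Th1 and Th2 cells and in naive ILC2s against the group labelled LTi and NK cells, and the cytotoxic list in every comparison that named it. They also were the regulatory T cell list in IL-33 ILC2s against Th2 cells, naive ILC2s against NK cells and CD8 against CD4 T cells, the T cell list in IL-33 ILC2s against Th2 cells, and the Th1 list in Th2 and Th17 against Th1 cells. The rest were the Th2 list in Th17 against Th2 cells, the ILC2 list against the group labelled LTi, the NF-kB list against NK cells, and the amino acid list in Th2 against CD4 T cells and CD8 against CD4 T cells.

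**Figure D5:**
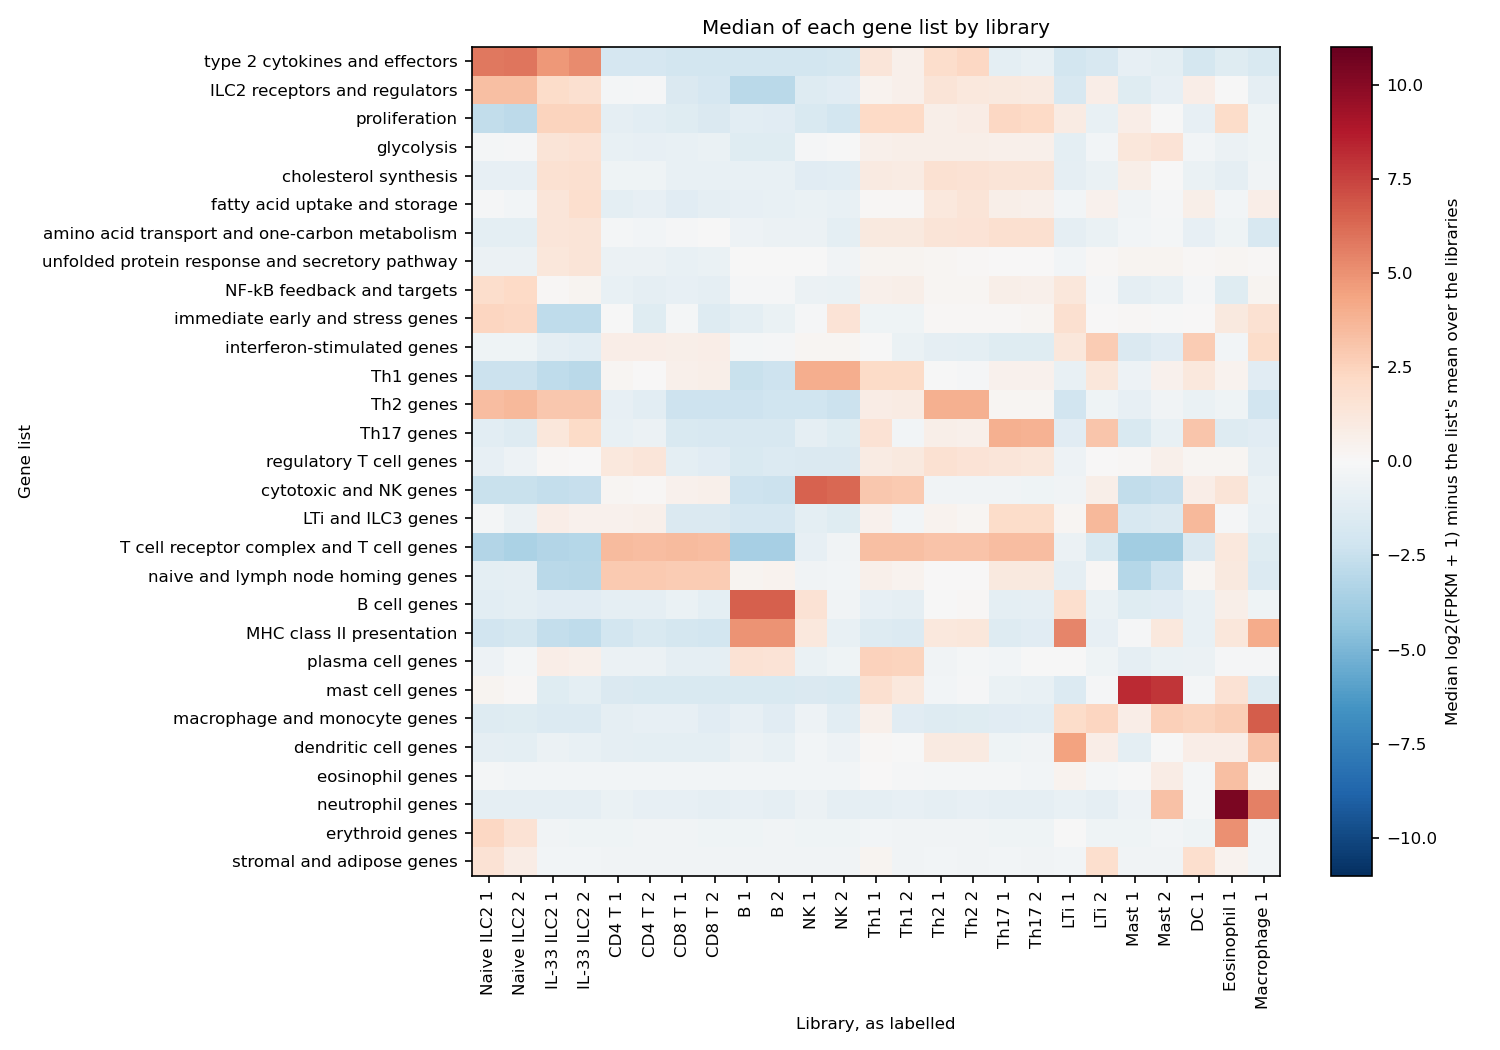
Median log2(FPKM + 1) of each of the 29 gene lists in each of the 25 libraries as labelled, less the list's mean over all libraries, on the colour scale. The immediate early list is high in both naive ILC2 libraries (7.43 and 7.31 as median log2(FPKM + 1)) and low in both IL-33 ILC2 libraries (2.24 and 2.26).

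Genes enriched in a cell type passed against every other group compared. Each value stands beside the mean of the nearest of these, though a single library can lie higher. Naive ILC2s, not compared with IL-33 ILC2s, had 409 such genes. The neutrophil chemokines Cxcl2 and Cxcl1 stood at 616 FPKM against 3.57 and 225 FPKM against 12.3. Others were Csf2 (1430.5 FPKM against 15.9), the matrix gene Dcn (79.4 FPKM against 0.366), the polarity gene Pard3 (66.1 FPKM against 0.274), the lipid droplet gene Hilpda (1670.3 FPKM against 39.9), Gadd45b (1607 FPKM against 57.6) and Igsf5 (137 FPKM against 3.19). Members of the fixed lists among them included 4 of 14 type 2 genes, 7 of 26 ILC2 receptors and regulators, 7 of 16 NF-kB genes, 5 of 26 immediate early genes, 3 of 5 erythroid genes and 2 of 15 stromal genes, Dcn and Dpt. In IL-33 ILC2s, Csf2 read 628 FPKM, Cxcl2 11.02 and Dcn 0.223.

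NK cells had 170 enriched genes, headed by Klra receptors: Klra8 (917 FPKM against 1.34), Klra18 (726 FPKM against 1.31), Klra9 (516 FPKM against 1.35) and Klra4 (374 FPKM against 1.34), with Klra14 and Klra21 after them (332 FPKM and 199 FPKM), whose near-identical sequences leave each gene's share uncertain. The egress receptor S1pr5 (240.1 FPKM against 1.06) and Klre1 (851 FPKM against 9.33) followed, and 11 of 18 cytotoxic and NK genes were among the enriched. B cells had 191, led by the antigen receptor gene Cd79a (1825 FPKM against 21.1), Ms4a1 (816 FPKM against 8.49), which encodes CD20, Ly6d (1149.5 FPKM against 14.6) and Faim3 (704 FPKM against 5.21). Next came Fcrla (254 FPKM against 2.89), the low-affinity IgE receptor Fcer2a (371 FPKM against 4.98), Cd19 (611 FPKM against 6.67) and the kinase Blk (232 FPKM against 3.76), and 13 of 14 B cell genes were enriched. For Cd79a, Ms4a1, Ly6d, Fcrla and Fcer2a the nearest group was NK cells, and NK library 1 held 39.5 FPKM of Cd79a where NK library 2 held 2.58. Without B cell library 1 or 2 the B cell count was 120 or 125, and without NK library 2 the NK cell count was 112.

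Mast cells had 448 enriched genes, with proteases at the head. In FPKM, they were the tryptase Tpsb2 (8826 against 2.08), nearly identical to Tpsab1, Tpsg1 (457 against 0.101) and the carboxypeptidase Cpa3 (17056 against 56.8). Beside them stood Fcer1a (4878 against 34.2), Igfbp5 (695 against 1.14), Rprm (491 against 2.25), Rab44 (358 against 1.89, but 97.4 in the eosinophil library) and Cd200r3 (541 against 3.78). Of the mast cell list, 13 of 16 were enriched, and the count of all enriched genes was 291 without mast cell library 2. The nearest group for Cpa3, Fcer1a, Rab44 and Cd200r3 was Th1 cells. The group labelled LTi had 51 enriched genes. Of these, Ccnd1 (cyclin D1) read 210 and 16.1 FPKM in LTi 1 and LTi 2 (against 1.07) and Adam23 87.2 and 4.02 (against 0.236). Others were, by mean, Pid1 (26.6 against 0.588), the macrophage gene Aif1 (34.2 against 1.11) and the Fc receptor Fcgr4 (14.5 against 0.468). Ctnnd2 (17.8), Rasa4 (67.6) and the interferon-induced Oasl2 (44.8) followed. That count was 286 without LTi library 1, 317 without LTi library 2, and 0 when the 3 single libraries were added as groups.

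The changes of ILC2s with IL-33 and of CD4 T cells on Th2 induction, which share no control libraries, were compared gene by gene. Rising in both, with log2 fold changes given for ILC2s first, were the desaturases Scd2 (7.10 and 4.14) and Scd1 (4.60 and 5.35) and the transcription factor Irf4 (4.21 and 5.29). Cyp11a1, Il9 and the desaturase Fads2, listed at 0 in both CD4 T cell libraries, and the CD30 gene Tnfrsf8, listed at 0 in both naive ILC2 libraries, also rose in both. Falling in both were Klf2 (-3.92 and -6.76), Ltb (-3.97 and -3.73), Sgk1 (-3.62 and -3.65) and Rasgrp2 (-3.50 and -6.00). Opposite in direction were Hmgn2 (3.24 and -2.72), Pdk1 (1.71 and -2.78), Atf3 (-5.63 and 5.00), Areg (-3.78 and 5.72), Crem (-3.70 and 3.94) and Tgm2 (-4.69 and 7.29). These examples were chosen after their values were seen, among the genes with the largest smaller change. Of 1522 genes that passed in both, 880 rose in both (638 if independent), 304 fell in both (129), 200 rose in ILC2s and fell in Th2 cells (525) and 138 did the reverse (157). Scalings that moved the ILC2 split were not run for these counts. Across all 13446 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.213 and Spearman's rho 0.238.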

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

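All tests in this part were chosen only after the results they examine were seen. The 3 single libraries enter no comparison, and in the libraries labelled dendritic cell and eosinophil gene lists of other cell types stood above the list of the cell type on the label. In the library labelled dendritic cell, whose dendritic cell list had a median log2(FPKM + 1) of 1.94, the medians were 5.52 for LTi and ILC3 genes, 4.04 for macrophage and monocyte genes, 3.48 for cytotoxic and NK genes, 2.42 for T cell genes and 2.20 for stromal genes. In the eosinophil library, whose own list had a median of 3.63, they were 11.36 for neutrophil genes, 5.56 for erythroid genes, 5.18 for T cell genes, 4.32 for macrophage and monocyte genes and 4.12 for cytotoxic and NK genes.

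The first pattern is that the libraries labelled LTi 1 and dendritic cell are out of place. Against LTi cells mixed with other cells in LTi 1, 6 of the 16 LTi and ILC3 genes at 10 FPKM or more in LTi 2 lay under 1% of their LTi 2 level there, Rorc at 0.204% and Il23r at 0%. Against the dendritic cell library holding cells high in MHC class II, as its gate states, that list had a median log2(FPKM + 1) of 3.03 in it and 8.81 in the lower B cell library. Exchanged labels of these libraries stay open and may explain both. DC 1 correlated with LTi 2 at r = 0.973, above the lowest replicate pair of other groups (0.953). No other pair of groups exceeded 0.961 (CD4 with CD8 T cells). Itgax read 410.1 FPKM in LTi 1 against 3.71. Col1a1, Xist and Ddx3y (values below) read alike in DC 1 and LTi 2 and apart in LTi 1. No biological explanation was tested.

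The second pattern is the transcripts of other blood cells in the eosinophil library, whose gate (Siglec-F+, Gr-1 low) should remove neutrophils and T cells. Neutrophil-lineage cells in the sample are a candidate source: 11 of 13 neutrophil genes were at 10 FPKM or more, with S100a8 at 59644, S100a9 at 50612 and Camp at 11926 FPKM, and the macrophage library had 11 such genes, with S100a8 lower (5316 FPKM) but Csf3r higher (91.7 against 49.5 FPKM) and Mmp8 too (48.6 against 1.02). T cells may be another, since 16 T cell genes stood near one common share of their mean in CD4 and CD8 T cells, with a median of 22.4%, a range of 13.8% to 33.8% and an SD of 0.346 on the log2 scale, Cd3g at 114 FPKM. With 1 library, neither says whether these transcripts came from whole cells or free RNA, and no biological explanation was tested.

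The third pattern is that most genes past the threshold were higher in IL-33 than in naive ILC2s. The tables argue against a few genes taking most of the FPKM of the naive libraries as the whole cause, since the median log2 fold change was 0.22 after small RNA hosts and the highest genes were left out of the sum (0.19 to 0.25 over the 4 pairs of libraries, against 0.04 at most between replicates), down from 0.51. They also argue against one scaling factor per library behind the fall of immediate early genes, as it scales every gene alike. The median log2 change of these 26 minus that of all genes was -4.77. Over the 4 pairs it was -4.89 to -4.58, against 0.18 at most between ILC2 replicates. Handling before RNA isolation and culture with IL-33 cannot be told apart, as no other group came from mesentery. The list median log2(FPKM + 1) was 7.31 in the lower naive library and 3.61 to 6.68 in 10 untreated spleen libraries without DC 1. LTi 1, open to an exchange with DC 1, read 6.82. Spleen replicates read 5.00 and 3.66 (CD4 T), 4.79 and 3.61 (CD8 T), 4.90 and 6.52 (NK) and 3.94 and 4.28 (B). Handling, IL-33 and culture stay open, untested.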

How the results depend on the processing

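Leaving out the group labelled LTi, with or without an estimated correlation, median centring and, for the activation correlation, rescaling were chosen after seeing the data; the other settings here were planned. Counts past the threshold of the 8 contrasts other than CD8 against CD4 T cells stayed within 1.5 times their value under every setting run, though their splits moved with scaling. CD8 against CD4 T cells went from 255 to 433 genes with pseudocount 0.1, 425 with only the compared groups fitted and 403 without the group labelled LTi, which removes its spread from the shared estimate. B cell enriched genes went from 191 to 307 without that group, and LTi enriched genes from 51 to 28 with the stricter filter and 0 with the single libraries as groups (limma; 15 at unadjusted p under 0.05), where the library labelled dendritic cell resembles LTi 2. List tests past the threshold went from 102 to 21 with an estimated correlation, and in the 8 contrasts without the group labelled LTi from 88 to 29 with it left out and the correlation estimated. Where no cause is given, the cause was not tested.

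With one library left out, the ranges that moved were 120 to 125 (B cells), 286 to 317 (LTi), 291 to 321 (mast cells) and 112 to 114 (NK cells) enriched genes; these fits lose a degree of freedom. Of 4091 recomputed values of named genes, 3972 kept direction and side of the threshold, 74 lost a call, 33 gained one and 12 changed sign, 1 of them past the threshold on either side: Il7r in naive ILC2s against the group labelled LTi was -1.68 without LTi replicate 1 (adjusted p = 0.00128) and 4.10 without replicate 2, since LTi 2 alone held its high level. The other sign changes were in that comparison Il22 and Il17f without LTi replicate 2 (-2.87 to 0.56 and -5.63 to 0.0963 with one library left out); in IL-33 against naive ILC2s Il5 (-0.29) and Il2ra (-0.84) with median centring, and Il2ra with equal sums (-0.0643) or one library left out (-0.0533 to 0.0797). In CD8 against CD4 T cells they were Cd3e and Lck with equal sums (-0.0338 and -0.0785), Cd3e with quantile normalization (-0.0841) and Lck with one library left out (-0.00466 to 0.0489). The correlation of the activation contrasts ranged from 0.194 to 0.251. Over 55 pairs of groups, the correlation of replicate differences had a median of 0.0141 (-0.193 to 0.162), and 6 pairs lay over 0.1. Among these were Th2 with CD4 T cells (0.162) and CD8 with CD4 T cells (0.144). Pairing by replicate number in those contrasts cannot be excluded. With the number as a block, IL-33 against naive ILC2s gave 5745 genes, Th2 against CD4 T cells 3384 and CD8 against CD4 T cells 239. Depth is unknown, so its limits cannot be given.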

Other observations

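No test in this part was run; all values were read after the data were seen. In the macrophage library, the highest genes relative to the other single libraries were Arhgef37 (72.96), Klra2 (199), Sirpb1a (165), F13a1 (309), Ear12 (27.9) FPKM, beside 22921 of Lyz2 and 562 of the macrophage growth factor receptor Csf1r. In the eosinophil library they were Hbb-b1 (199), Hba-a2 (150.4), Prg2 (195), Mpo (3038), Elane (4943) FPKM, of which the globins have near-identical copies, Prg2 encodes a major eosinophil granule protein, and Mpo and Elane encode a peroxidase and a protease of neutrophil precursors. Other eosinophil genes read 23.7 (Siglec5), 36.5 (Ear2), 6.76 (Epx), 4.86 (Ccr3) and 0.631 FPKM (Il5ra). In the library labelled dendritic cell (DC 1) they were Actr3 (268), Gzmc (1119.5), Olfr523 (153), Rorc (169), Col6a1 (105) FPKM, where LTi 2 had 1154 of Gzmc, 167 of Rorc and 97.4 of Col6a1. The collagen gene Col1a1 read 68.6 FPKM in DC 1, 65.1 in LTi 2 and 0.0318 in LTi 1.

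Traces of other lineages stood in some replicated libraries. NK libraries 1 and 2 held 39.5 and 2.58 FPKM of Cd79a and 14.7 and 0.787 of Cd19. Th1 libraries held 65.6 and 48.01 FPKM of the mast cell protease Cpa3. Th1 library 1 stood above Th1 library 2 in C1qa (5.15 and 0 FPKM), Col1a1 (4.24 and 0.0837), Lyz2 (18.3 and 1.59) and Rorc (10.1 and 1.34). S100a8 (0 and 1.20 FPKM) and Hbb-b1 (0.00697 and 6.31) went the other way. Th1 libraries 1 and 2 had r = 0.824 and 0.784 with LTi 2. Th2 libraries held 31.2 and 22.4 FPKM of Prg2, 5.83 and 7.51 of Cd19 and 0.520 and 0.485 of the B cell gene Ms4a1. Mast cell libraries held 3.56 and 447 FPKM of S100a8. Xist and Ddx3y read 0.0322 and 23.7 FPKM in LTi 1, 18.9 and 13.3 in LTi 2, and 18.6 and 12.3 in DC 1.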
